A study of Mus musculus with 18 samples.

How the data were processed

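Poly-A RNA was sequenced from liver, brain and testis of adult male C57BL/6 mice aged 8 weeks, wild type (WT) or knockout (KO) for Pcgf6, with 3 libraries per genotype and tissue and 18 libraries in all. In every tissue the labels number the WT libraries 1 to 3 and the KO libraries 4 to 6, and these numbers are used as names here. Per the submitters' processing notes, reads were aligned to mm10 with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3, and the submitters tested them with DESeq2 1.16.1. The authors deposited FPKM (fragments per kilobase of gene length, scaled by a library size) for 52636 genes per library.

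Every deposited FPKM value, multiplied by gene length, was a whole multiple of 1 step per library within a tolerance of 0.01 reads. Read counts per gene were therefore recovered and summed to give the depth, which lay between 18990130 and 23529098 reads per library. The library sizes behind the deposited FPKM were not the plain totals: they matched median-of-ratios size factors over the 18 libraries, taken from 14876 genes with a read in each. A tissue rich in a few transcripts therefore carries its scaling into the FPKM of all its genes, so FPKM is compared here within a tissue. Shares of another tissue's FPKM are the exception and carry this scaling; the library total over the implied size was 1.44 to 1.52 in liver, 0.806 to 0.835 in brain and 0.823 to 0.969 in testis. Of the 52636 genes, 11110 had no read in any library, and 103 symbols occurred more than once.

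The design had been written for read counts. Because the files hold FPKM, edgeR was not used, and DESeq2 was not used beyond what the submitters ran. Each tissue was tested with limma 3.58.1 (R 4.3.3) on log2(FPKM + 0.1) with a mean-variance trend, on genes with at least 10 reads in at least 3 of the 6 libraries. P values were adjusted by the method of Benjamini and Hochberg, and a gene is said to have risen, fallen or been called at an adjusted p under 0.05. Log2 fold changes are KO minus WT and are given with their limma standard error (SE); FPKM is given as mean ± SD over 3 libraries. Difference tests between tissues used limma on the 12 libraries of both tissues and the genes tested in both.

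Fixed gene lists, 56 in number, covered targets of the repressive complex that contains Pcgf6, germ cell programmes, metabolism, stress and cell types of the 3 tissues. Of their symbols 3 were matched through a synonym and 4 were not matched. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance in one direction. Counts said to be adjusted over the list alone adjust only over that list's tested genes. Sums of CPM (reads scaled by the library total) and scores per library were compared with exact two-sided permutation tests, whose smallest p with 3 against 3 libraries is 0.1. Testis-specific genes were defined as those with at least 10 CPM in WT testis and at least 100 times the level in WT of the other somatic tissue, so the set tested in liver was defined against brain and the set tested in brain against liver. For these sets limma used a looser filter, at least 10 reads summed over the 6 libraries, and adjusted within the set. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the remaining steps.

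Genes are named by a rule: Pcgf6 itself, the 10 largest called changes in each direction with a mean of at least 1 CPM and no overlap between groups, up to 3 called members of each list, genes called in all 3 tissues, and 10 germ cell genes in liver and brain (Ddx4, Dazl, Mael, Tdrkh, Stk31, Slc25a31, Taf7l, Sycp3, Tex101 and Hormad1). Members given as examples of a called list without being called themselves, and other genes outside this rule, were chosen after their values were seen. Where all WT libraries had 0 reads, the fold is a lower bound against a floor of 3 reads per library; with 1 to 3 reads in a group, the ratio of reads is given with its 95% interval. These bounds and intervals cover counting error only.

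The steps were tested on simulated reads for 200 changed genes per tissue. At 2-fold, limma recovered 50.8% in liver (14115 genes run), 67.2% in brain (17915) and 46% in testis (22271); at 8-fold it recovered 93.7%, 98.4% and 93.3%. False calls were 9 of 158, 16 of 188 and 12 of 153 calls in the same order, and none of 20 unchanged lists was called in any tissue. The simulated genes varied independently of each other, so this does not test the error rate for real lists, whose genes can move together. The difference between tissues had been planned as a single fit over 18 libraries, which gave 16.2% (brain minus liver), 27% (testis minus liver) and 19.2% (testis minus brain) false calls on simulated reads. It was replaced by the fit to 12 libraries, with 7.53%, 9.67% and 10.4% false calls, after several forms of the fit had also been run on the real libraries.

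Whether numbers pair libraries was checked by correlating deviations from group means across genes, which are not independent replicates. The numbers in the names of the value columns pair each WT library with the KO library 3 numbers higher. In liver these pairs correlated at 0.354, 0.162 and 0.299, all above 0.1, and were taken as paired; in brain (0.0949, -0.0848 and 0.252) and testis (0.0849, -0.0646 and 0.0902) they were not. The title numbers shared by tissues correlated from 0.118 to 0.228 between liver and testis, all 6 above 0.1, and were taken as paired there. Between liver and brain they ranged from 0.0547 to 0.236, and each number correlated best with its own number among libraries of its genotype. Between brain and testis they ranged from -0.00262 to 0.242, and numbers 2 and 3 did not correlate best with their own. The cut of 0.1 left these tissues unpaired, which does not show that their libraries come from different mice. The main fits and list tests did not use any pairs, and fits with the numbers as a block are given as alternatives.

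Gene lists, the naming rule, the use of camera on the lists, the permutation tests of sums and most alternatives were fixed before the data were examined; the test of single genes and the fit for differences between tissues were not. Alternatives covered other scalings, limma voom with and without quality weights, other filters, all 18 libraries in 1 fit, a replicate block, and leaving out each library in turn. Chosen after seeing the data were the use of limma on log2 FPKM, pseudocounts of 0.01 and 1 FPKM, the block by column number, voom for the differences between tissues, a filter of 2 libraries in leave-one-out fits, a term for Alb in brain, list scores within the pairs of liver libraries, and the deposited library sizes for the germline sum. The TMM scaling and a Wald test on counts were not run. Lists with fewer than 5 tested members, exon-level reads and splice forms were not analysed here, and values of some single list members are not reported.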

Results

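Poly-A RNA from liver, brain and testis of adult male mice was profiled to ask which genes depend on Pcgf6, a subunit of the polycomb complex PRC1.6 that keeps germ cell genes silent outside the germ line. Each tissue had 3 WT and 3 KO libraries, 18 in all. Depth ranged from 18990130 to 23529098 reads in liver, from 20759022 to 23183662 in brain and from 20098777 to 23335596 in testis. Mitochondrial transcripts made up 5.23 to 5.75% of reads in liver, 3.85 to 4.32% in brain and 0.772 to 1.04% in testis.

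Pcgf6 itself was lower in KO than in WT libraries of all 3 tissues, and KO libraries kept reads of the gene. Pcgf6 (ENSMUSG00000025050) lies on mm10 chromosome 19 from 47033619 to 47050845. In liver it measured 4.91 ± 0.79 FPKM in WT and 1.92 ± 0.65 in KO (SD, n = 3 each), which is 39.0% of WT. In testis it measured 20.9 ± 1.25 and 9.93 ± 0.59 FPKM, 47.6% of WT. In brain the KO level was 79.2% of WT, at 3.98 ± 0.60 against 5.02 ± 0.38 FPKM. Every KO library lay below every WT library in each tissue, a separation that chance gives to 10% of genes. None of the log2 fold changes passed adjustment over all tested genes in limma, at -1.35 ± 0.24 in liver (SE, adjusted p = 0.485), -0.34 ± 0.12 in brain (adjusted p = 1.00) and -1.06 ± 0.09 in testis (adjusted p = 0.0638). Taken as a single gene fixed in advance, Pcgf6 had unadjusted limma p values of 0.000844 in liver, 0.0243 in brain and 5.71e-06 in testis. Over 17 alternatives the adjusted p ran from 0.00233 to 0.944 in liver, with 1 past the threshold, and from 0.000403 to 0.707 in testis, with 3 past it; none of 18 passed in brain. The files give 1 value per gene and cannot show which exons the remaining reads cover.

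**Figure D1:**
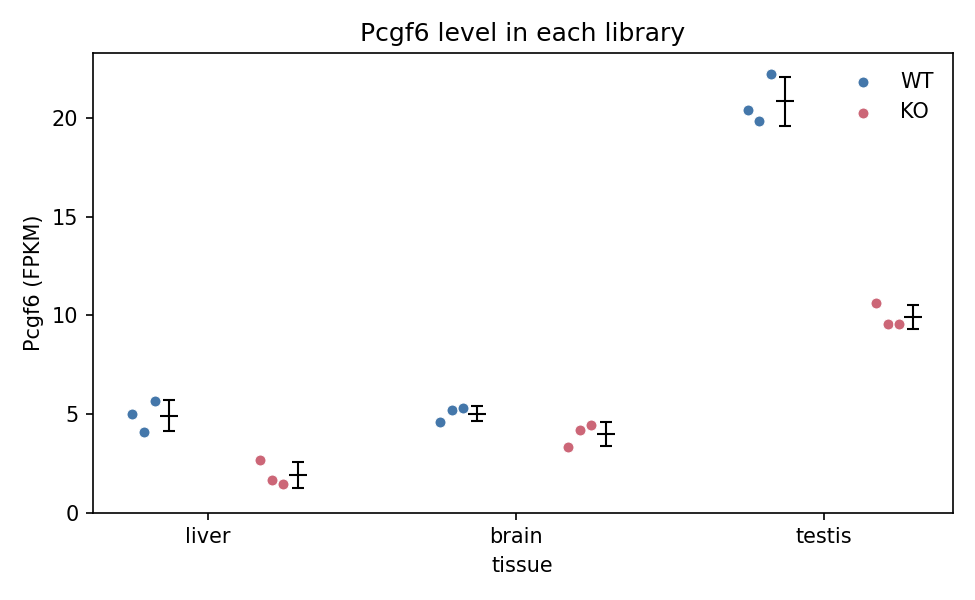
Pcgf6 level in FPKM (vertical axis) in each library of liver, brain and testis, for WT and KO; points are single libraries, black dashes are means of 3 and bars are SD. KO means were 39.0% of WT in liver, 79.2% in brain and 47.6% in testis, and no KO library reached the lowest WT library of its tissue.

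In liver, 3 genes rose in the KO in the fit without pairs, and all 3 belong to the germ line. With the pairs of liver libraries as a block in limma, Slc25a31 was not called (adjusted p = 0.122). Mael, needed for silencing of transposons in male germ cells, had no read in any WT library and 15.0 ± 5.42 FPKM in KO (SD, n = 3), at least 125-fold higher. Syce1, a component of the synaptonemal complex of meiotic chromosomes, went from 0 reads to 1.80 ± 0.30 FPKM, at least 12.6-fold higher. Slc25a31, an ADP/ATP carrier of the male germ line, was 63.9 times higher, at 4.63 ± 1.51 against 0.07 ± 0.06 FPKM. All KO libraries lay above all WT libraries for each of the 3. Their limma log2 fold changes were 7.17 ± 0.30 for Mael (adjusted p = 0.000639), 4.23 ± 0.21 for Syce1 (adjusted p = 0.00104) and 4.80 ± 0.38 for Slc25a31 (adjusted p = 0.0203). These values depend on the pseudocount, since WT is at or near 0, and over 17 alternatives ran from 3.94 to 10.5, from 1.48 to 7.48 and from 2.36 to 6.43 in the same order. Mael (ENSMUSG00000040629) lies on chromosome 1 from 166201201 to 166238747, Syce1 (ENSMUSG00000025480) on chromosome 7 from 140777229 to 140787852, and Slc25a31 (ENSMUSG00000069041) on chromosome 3 from 40708855 to 40726096. Of 14124 genes tested no gene fell, 618 had an unadjusted p under 0.05 and 9.52% were separated by genotype, against 10% by chance. Limma voom called 2 genes, and a single fit over all 18 libraries called 107.

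Other germ cell genes in liver did not pass the test. Ddx4, a germ cell RNA helicase, had 2 reads in WT and 81 in KO, a ratio of 42.9 with a 95% interval from 11.5 to 361 (log2 fold change 2.73 ± 0.30, adjusted p = 0.117); of 16 alternatives, with adjusted p up to 0.759, it passed in 1, the fit over all 18 libraries (0.000223). Tex11 had 0 reads in WT and 40 in KO (adjusted p = 0.145), and Tdrkh measured 0.74 ± 0.18 against 1.48 ± 0.25 FPKM (adjusted p = 0.686). Sycp3 measured 0.84 ± 0.51 and 0.54 ± 0.29 FPKM (adjusted p = 1.00). Too few reads for a test were seen for Dazl (3 in WT and 6 in KO), Stk31 (0 and 2), Tex101 (1 and 3), Hormad1 (0 and 1) and Taf7l (0 and 0). The call for Slc25a31 was lost without WT 2, WT 3, KO 4 or KO 6, with adjusted p from 0.0231 to 0.108 over the 6 leave-one-out fits, and it was 0.122 with the pairs of liver libraries as a block. Over all 17 alternatives Syce1 stayed called in 17, Mael in 15 and Slc25a31 in 8; voom, with and without quality weights, ended the call of Mael (adjusted p = 0.118 and 0.0844), and voom, a pseudocount of 0.01 and no filter that of Slc25a31 (adjusted p up to 0.465).

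In KO liver camera called 11 of 31 lists, among them germ cell, metabolic and immune programmes, and 0 with an estimated correlation. Other splits of the 6 liver libraries called 5 to 15 lists. Of the called lists, mean scores per library separated the genotypes only for PRC1.6 germline targets, the piRNA pathway and fetal liver genes (exact permutation p = 0.1 each). The fixed list of PRC1.6 germline targets rose, with 9 of 10 tested members higher (median log2 fold change 0.81, also with the 2 genes at 0 in WT set to their bound; adjusted p = 4.09e-14; 0.0789 with an estimated correlation). Of these, 2 were called over all genes and 7 when adjusted over the list alone. The list's adjusted p was 0.00204 in fry, which does not set it against other genes. The piRNA pathway was called up with 5 of 9 members higher (median 0.02, mean 1.23, adjusted p = 0.00171; 0.286 with an estimated correlation; median -0.00075 without KO 4), with 1 gene called and 3 adjusted over the list alone. Meiotic recombination genes were not called by camera (median -0.05, mean 0.31, adjusted p = 0.495; fry 0.00312), Syce1 being the 1 gene called over all genes and over the list alone.

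Genes of cholesterol synthesis and uptake fell together in KO liver, with all 24 lower (median log2 fold change -0.51, adjusted p = 2.61e-11; 0.577 with an estimated correlation) and 0 called singly or adjusted over the list alone. The list's mean score per library was -0.12, 0.69 and 0.23 in WT 1 to 3 and -0.33, -0.62 and 0.14 in KO 4 to 6, so the groups overlapped (exact permutation p = 0.2). Within the pairs of liver libraries (WT 1 with KO 4, WT 2 with KO 5 and WT 3 with KO 6) it was lower in KO in 3 of 3 (mean difference -0.54 ± 0.67, SD). The scores of the other called liver lists were higher in KO in 3 of 3 pairs, except mitochondrially encoded genes with 2 of 3; the smallest sign-flip p that 3 pairs can give is 0.25. Fatty acid oxidation and PPARa targets rose, with 24 of 28 higher (median 0.23, adjusted p = 1.47e-05; 0.609 with an estimated correlation). Cyp4a10, a fatty acid hydroxylase, measured 98.3 ± 37.8 and 204 ± 55.1 FPKM, and Vnn1, at 11.7 ± 1.64 and 27.4 ± 7.90, was the 1 gene called when adjusted over the list alone. Fetal liver genes rose with all 10 higher (median 0.34, adjusted p = 0.0139; 0.412 with an estimated correlation), among them Spp1 at 31.1 ± 10.7 and 47.4 ± 14.7 FPKM, 0 adjusted over the list alone.

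Further liver lists called up depended on single libraries. Macrophage and neutrophil genes (18 of 19 higher, median 0.24, adjusted p = 0.00186; 0.745 with an estimated correlation) included H2-Aa, an antigen-presenting molecule, at 11.5 ± 2.02 and 21.7 ± 7.62 FPKM; without WT 1 the list's median turned to -0.12 and its adjusted p was 0.958. Lymphocyte genes (5 of 6 higher, median 0.44, adjusted p = 0.0199; 0.609 with an estimated correlation) lost the call without KO 5 (0.110), and imprinted genes (16 of 21, median 0.12, adjusted p = 0.0135; 0.434 with an estimated correlation) without KO 6 (0.0970). Peg10, a paternally expressed gene, was the 1 imprinted gene called when adjusted over the list alone, at 0.0893 ± 0.00953 and 0.293 ± 0.0382 FPKM. Acute phase and complement genes (20 of 27, median 0.14, adjusted p = 0.00827; 0.424 with an estimated correlation) lost it without WT 3 (0.103) or KO 4 (0.142). Bile acid genes (15 of 20, median 0.13, adjusted p = 0.0112; 0.424 with an estimated correlation) lost it without WT 2 (0.111) or WT 3 (0.0857). Mitochondrially encoded genes (22 of 28, median 0.13, adjusted p = 0.0231; 0.745 with an estimated correlation) lost it without WT 2 (0.622), KO 4 (0.123) or KO 5 (0.0756). Apart from the imprinted genes, 0 members of these lists were called when adjusted over the list alone. Of the lists not called, Kupffer cell genes came closest (adjusted p = 0.0976), and the other subunits of PRC1.6 had an adjusted p of 0.438.

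In brain, 15 genes passed the test, 12 up and 3 down, and the 3 germ cell genes that rose in liver were among them. Leaving out 1 library gave 8 to 11 genes, and limma voom with quality weights gave 25. Mael measured 9.0 ± 2.51 FPKM in KO and 0.09 ± 0.11 in WT, 98.7 times higher (SD, n = 3). Slc25a31 was 55.8 times higher (1.59 ± 0.61 against 0.03 ± 0.02) and Syce1 8.99 times higher (1.27 ± 0.23 against 0.14 ± 0.07). Henmt1, which methylates piRNAs at their ends, rose from 0.25 ± 0.02 to 1.33 ± 0.14 FPKM, and Rbm46, a germ cell RNA-binding protein, from 0.18 ± 0.03 to 0.89 ± 0.18. On the X chromosome, Xlr4b rose from 0.06 ± 0.05 to 3.17 ± 0.28 FPKM, and Xlr4c had 1 read in WT and 285 in KO, a ratio of 296 with an interval from 52.7 to 11740.

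The log2 fold changes of these brain genes were 5.69 ± 0.41 for Mael, 3.67 ± 0.26 for Slc25a31 and 2.01 ± 0.14 for Henmt1 (SE, adjusted p = 0.00264 for each), and 2.53 ± 0.23 for Syce1 (adjusted p = 0.0142). They were 1.81 ± 0.19 for Rbm46 (adjusted p = 0.0224), 4.02 ± 0.17 for Xlr4c (adjusted p = 0.00046) and 4.38 ± 0.23 for Xlr4b (adjusted p = 0.00073), with every KO library above every WT library. The pseudocount sets part of these sizes as well: over 18 alternatives Mael ran from 3.17 to 7.33, Slc25a31 from 1.31 to 5.49, Henmt1 from 0.891 to 2.37, Syce1 from 0.989 to 3.16, Rbm46 from 0.676 to 2.30, Xlr4c from 1.37 to 7.12 and Xlr4b from 1.97 to 5.84. Xlr4c (ENSMUSG00000031362, X, 73233688 to 73243130) and Xlr4b (ENSMUSG00000067768, X, 73214333 to 73222453) are near-identical copies, so the division of reads between them is uncertain. Gm4779 (4.90 ± 0.28, adjusted p = 0.000882) and its neighbour on the X chromosome, 8030474K03Rik (4.90 ± 0.29, adjusted p = 0.00104), rose to 8.64 ± 2.90 and 3.57 ± 1.04 FPKM. Henmt1 (ENSMUSG00000045662) lies on chromosome 3 from 108939873 to 108960774 and Rbm46 (ENSMUSG00000033882) on chromosome 3 from 82837228 to 82876483.

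Other genes also changed in brain. Ide, the insulin-degrading enzyme, fell from 11.1 ± 0.59 to 6.91 ± 0.31 FPKM (log2 fold change -0.67 ± 0.06, adjusted p = 0.0180); it lies on chromosome 19, as Pcgf6 does, from 37268743 to 37337852 (ENSMUSG00000056999). Klk6, a protease of oligodendrocytes, rose from 6.42 ± 0.44 to 10.9 ± 0.78 (0.75 ± 0.08, adjusted p = 0.0220). Gabra2, a GABA receptor subunit, rose from 5.81 ± 0.14 to 8.38 ± 0.25 (0.52 ± 0.06, adjusted p = 0.0274). The transcribed pseudogene Rps4l (ENSMUSG00000063171) fell from 11.4 ± 1.87 to 1.69 ± 0.20 FPKM (-2.68 ± 0.13, adjusted p = 0.000679). Mir378b (-0.77, adjusted p = 0.0220) and Obox3-ps7 (1.91, adjusted p = 0.0220) complete the 15. For each gene of this paragraph the genotypes did not overlap.

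Of 17922 genes tested in brain, 800 had an unadjusted p under 0.05 and 9.08% were separated by genotype, against 10% by chance; a single fit over all 18 libraries called 40. Among the remaining germ cell genes, Ddx4 measured 0.69 ± 0.27 and 3.94 ± 1.61 FPKM (2.35 ± 0.33, adjusted p = 0.111; 0.00122 to 0.437 over 18 alternatives), Taf7l 0.09 ± 0.07 and 0.82 ± 0.45 (adjusted p = 0.522) and Dazl 0.89 ± 0.17 and 0.62 ± 0.12 (adjusted p = 1.00). Tdrkh (0.13, adjusted p = 1.00) and Sycp3 (-0.01, adjusted p = 1.00) were close to 0 on the log2 scale, and Stk31 (4 and 12 reads), Tex101 (2 and 15) and Hormad1 (1 and 1) did not pass the read filter of this fit. Ddx4 passed in 4 of these alternatives, among them voom (adjusted p = 0.0444), voom with quality weights (0.0439) and the fit over all 18 libraries (0.00122). Rbm46, Klk6 and Ide lost their calls whichever of the 6 libraries was left out, with highest adjusted p of 0.173, 0.162 and 0.140, and Syce1 without WT 2, WT 3, KO 4, KO 5 or KO 6 (highest 0.109). Over 18 alternatives Mael stayed called in 17 (adjusted p = 0.102 with a pseudocount of 0.01), Syce1 and Ide in 11 and Rbm46 and Klk6 in 9, while Xlr4c, Xlr4b, Gm4779, 8030474K03Rik, Henmt1, Slc25a31 and Rps4l stayed called in all. The brain libraries WT 3, KO 5 and KO 6 carried the liver transcript Alb at 9.55, 4.24 and 5.47 FPKM, against 0.0154, 0.0472 and 0.410 in WT 1, WT 2 and KO 4.

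**Figure D2:**
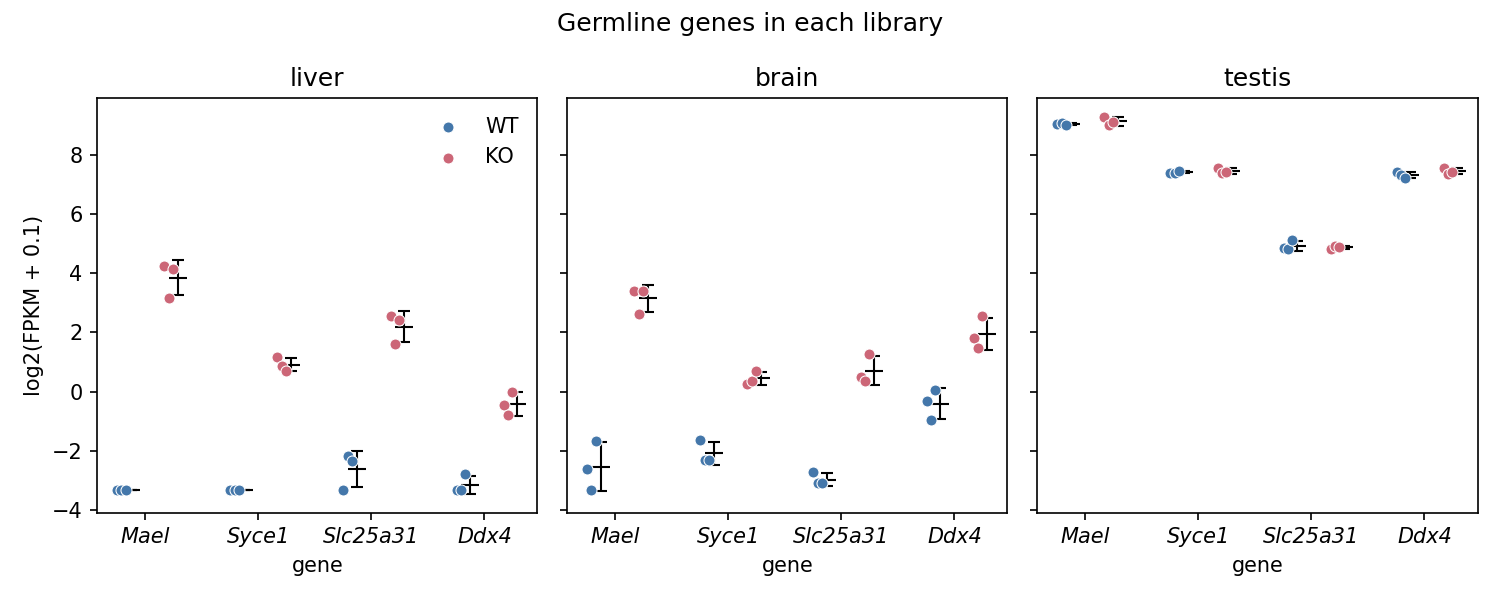
Levels of Mael, Syce1, Slc25a31 and Ddx4 as log2(FPKM + 0.1) (vertical axis) in WT and KO libraries of liver, brain and testis; points are single libraries, black dashes are means of 3 and bars are SD. In liver and brain each gene was higher in all KO than in all WT libraries, while in testis Mael measured 522 ± 13.8 FPKM in WT and 558 ± 56.7 in KO.

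Among the gene groups of the brain, camera called 11 of 33 lists, 7 up and 4 down. PRC1.6 germline targets (13 of 20 higher, median log2 fold change 0.15, mean 0.76, adjusted p = 0.000375; 0.222 with an estimated correlation) had 2 genes called and 5 adjusted over the list alone. The piRNA pathway (15 of 20, median 0.17, adjusted p = 3.95e-06; 0.177 with an estimated correlation) likewise had 2 called and 5 adjusted over the list alone, among its members Gpat2 at 0.21 ± 0.14 and 1.22 ± 0.19 FPKM (adjusted p = 0.138). Meiotic genes (13 of 20, median 0.13, adjusted p = 0.00255; 0.222 with an estimated correlation) had 1 called and 2 adjusted over the list alone; without KO 6 the list's adjusted p was 0.0634. Oligodendrocyte and myelin genes rose with all 20 higher (median 0.21, adjusted p = 1.93e-10; 0.361 with an estimated correlation), 3 adjusted over the list alone. Mbp, the myelin basic protein, measured 350 ± 14.9 and 421 ± 29.6 FPKM. Cholesterol genes, which fell in liver, rose in brain, with 22 of 24 higher (median 0.13, adjusted p = 3.95e-06; 0.361 with an estimated correlation; 0 adjusted over the list alone); the difference between the tissues was not tested for lists.

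Regional and other cell type lists were also called by camera in brain, where other splits of the 6 libraries called 1 to 11 lists. Cerebellar genes rose (17 of 18, median 0.32, adjusted p = 1.2e-07; 0.549 with an estimated correlation), Fat2 of granule cells measuring 6.58 ± 1.6 and 9.37 ± 0.41 FPKM, and WT 3 had the lowest mean score of this list at -0.54. Inhibitory neuron genes fell (13 of 17, median -0.12, adjusted p = 0.000386; 0.361 with an estimated correlation), with Dlx1, a transcription factor of these neurons, at 6.75 ± 0.75 and 4.83 ± 0.75. Striatal genes were all 16 lower (median -0.10, adjusted p = 0.000704; 0.575 with an estimated correlation), a call lost without WT 1 (0.249). Hox genes (7 of 7 higher, median 0.85, adjusted p = 0.00507; 0.610 with an estimated correlation), which mark hindbrain and spinal cord, lost it without WT 1 (0.249) or KO 6 (0.0971). Ribosomal protein genes (59 of 80 lower, median -0.05, adjusted p = 0.00581; 0.890 with an estimated correlation) turned to medians of 0.00 without WT 2 and 0.01 without KO 6. Lymphocyte genes (5 of 7 lower, median -0.09, adjusted p = 0.0182; 0.361 with an estimated correlation) lost it without KO 5 (0.157, median 0.02) or KO 6 (0.0579). Their antibody genes Ighm, at 6.31 ± 1.01 and 3.57 ± 1.2, and Ighg2c were the 2 called when adjusted over the list alone; the other lists of this paragraph had 0. Of the lists not called, genes of the hypothalamus and pituitary came closest (adjusted p = 0.0832).

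In testis, where these germ cell genes are normally active, 1 gene passed the test and none of the germline targets did. Gm5815, a processed pseudogene (ENSMUSG00000046952, chromosome 17, 58593659 to 58594843), fell from 9.0 ± 1.90 to 1.01 ± 0.14 FPKM (SD, n = 3). Its log2 fold change was -3.02 ± 0.19 in limma (adjusted p = 0.0161, lower in all 3 KO libraries), and as a pseudogene its reads may be shared with its parent gene. It was not particular to testis: brain had 0.699, 0.715 and 1.05 FPKM in WT and 0.101, 0.310 and 0.157 in KO, without a call. In liver it had at most 5 reads in any library. The call in testis was lost without KO 4, KO 5 or KO 6, with adjusted p up to 0.257, and with no filter on low reads (0.0579). Mael measured 522 ± 13.8 and 558 ± 56.7 FPKM, Syce1 170 ± 4.59 and 175 ± 10.8, Slc25a31 30.3 ± 3.81 and 29.1 ± 0.89, and Ddx4 159 ± 10.8 and 175 ± 12.4, none of them called. Of 22341 genes tested, 922 had an unadjusted p under 0.05 and 11.9% were separated by genotype, against 10% by chance. Limma voom called 2 genes, and a single fit over all 18 libraries called 37. Testis WT 3 stood apart from the other testis libraries, with a score of 64.9 on a first component holding 43.1% of the variance, against -21.4 to -7.05.

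Camera called 7 of 28 gene groups in testis, each with an adjusted p of 0.903 with an estimated correlation and in several cases resting on WT 3. Ribosomal protein genes fell (76 of 83 lower, median -0.11, adjusted p = 1.35e-06), and without WT 3 their median was 0.02 (adjusted p = 0.712). Sertoli cell genes fell (25 of 28, median -0.19, adjusted p = 2.78e-05; 0.0644 without WT 3), with Defb36 at 76.9 ± 20.1 and 50.8 ± 4.82 FPKM. Spermatogonial genes fell (17 of 22, median -0.17, adjusted p = 0.000232), with Stra8, which starts meiosis, at 9.0 ± 1.70 and 6.52 ± 0.98. Hox genes fell (16 of 19, median -0.26, adjusted p = 2.99e-05), with Hoxd9 at 3.14 ± 0.96 and 2.03 ± 0.03. Elongating spermatid genes rose (28 of 30, median 0.15, adjusted p = 0.0231), a call lost without WT 3 (0.721, median 0.02) or KO 4 (0.584). Round spermatid genes rose (20 of 25, median 0.10, adjusted p = 0.0231), a call lost without WT 3 (0.390), KO 4 (0.189) or KO 6 (0.525). Genes of the epididymis, the duct beside the testis, fell (4 of 5, median -0.82, adjusted p = 0.0231). Its sperm coat protein Crisp1 measured 2.09, 19.2 and 133 FPKM in WT 1 to 3 and 0.105 ± 0.064 in KO; it was the 1 gene of these groups called when adjusted over its list alone. PRC1.6 germline targets (35 tested, median -0.02, adjusted p = 0.210) and the piRNA pathway (26 tested, median 0.07, adjusted p = 0.537) were not called, nor were p53 targets, the closest of the rest (adjusted p = 0.106).

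Summed over all 35 germline targets, expression was 3.07 times higher in KO liver (51.3 ± 11.1 against 16.7 ± 1.90 CPM) and 1.58 times higher in KO brain (115 ± 17.8 against 72.9 ± 1.61 CPM). In both tissues every KO library exceeded every WT library, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. In testis the sums were 7748 ± 706 CPM in WT and 7389 ± 83.9 in KO (exact permutation p = 0.8). Without Mael the difference in liver was 17.2 CPM in place of 34.6, so Mael made up about as much of it as all other targets together.

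Few genes specific to the testis, fixed targets included, rose in KO liver or brain, with each set defined without the tissue it was tested in. Of 1563 genes specific to testis against brain, 344 were tested in liver and 6 rose when adjusted within the set: Mael, Syce1, Slc25a31, Ddx4 (adjusted p = 0.00440), Gm9795 (0.0139) and Cc2d2b (0.0362). The looser filter lets in genes near the floor: Gm9795 had 1 read in WT and 15 in KO liver, and Cc2d2b 12 and 77. Of 2406 specific to testis against liver, some of which WT brain expresses, 1522 were tested in brain and 5 rose: Mael, Slc25a31, Henmt1, Syce1 and Rbm46. The KO mean was above WT in 234 of 344 genes in liver and in 885 of 1522 in brain. The summed level of the set was 6343 ± 296 CPM in WT and 7357 ± 402 in KO liver (exact permutation p = 0.1), and 55800 ± 682 and 55740 ± 810 in brain (exact permutation p = 1). The sum in liver also holds genes that WT liver expresses, such as Gm5617 at 47.7 FPKM in WT and 39.9 in KO. Whether its difference comes from genes silent in WT liver was not tested. Without KO 4, 37 genes of the set tested in liver were called; its most abundant gene in testis, Prm1, measured 0 FPKM in liver KO 4, 2.06 in KO 5 and 2.14 in KO 6.

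Differences of the genotype effect between tissues were tested gene by gene, and not for lists. Testis minus liver, 6 of 13133 genes differed, all with a lower log2 fold change in testis, and testis minus brain 10 of 15962, of which 9 were lower and Rps4l was higher. Mael measured 0 FPKM in WT liver and 522 in WT testis. For such genes the same gain in FPKM is a large log2 change in liver and a small one in testis. Their differences therefore do not show that loss of Pcgf6 acts less in testis. Mael differed by -7.07 from liver (adjusted p = 1.90e-07; -10.4 to -3.84 over 13 alternatives) and by -5.59 from brain, Syce1 by -4.20 and -2.49, and Slc25a31 by -4.85 and -3.72 on the log2 scale. Limma called 0 of 12922 genes for brain minus liver, where 625 had an unadjusted p under 0.05 and voom also called 0. Of the genes called in brain alone, Xlr4b had a log2 fold change of 4.66 in liver (adjusted p = 0.349), Gm4779 5.05 (0.686), Rps4l -2.43 (0.406) and Ide -0.68 (0.145), with no overlap between genotypes. With title numbers as a block, which pair liver with testis, Tex11 was no longer called (adjusted p = 0.0773; up to 0.866 over 13 alternatives) and 5 genes remained.

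The genes that rose in liver and brain overlapped. Among 12922 genes tested in both tissues, 3 rose in liver and 7 in brain, and all 3 were shared (Mael, Syce1 and Slc25a31) against 0.00163 expected (Fisher's exact p = 9.73e-11). That p treats genes as independent and also the tissues, which may come from the same mice. Of 10 splits of the title numbers, the same in both tissues, 2 shared at least 3 called genes, the real one included. Across genes, which are not independent replicates, log2 fold changes correlated at 0.305 between liver and brain, 0.0808 between liver and testis and 0.0409 between brain and testis. Other splits of the title numbers, the same in both tissues, gave 0.0816 to 0.267, 0.0738 to 0.224 and 0.0417 to 0.184, so positive correlations also arise from splits other than genotype.

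Genes around Pcgf6 on chromosome 19 lay close to 0 as a group. Within 5 Mb, 80 genes were tested in liver (median log2 fold change 0.02), 95 in brain (0.04) and 112 in testis (0.02), and limma called 0 in each; 4, 5 and 4 of them had an unadjusted p under 0.05. The median over these genes in brain was 0.04 without Pcgf6 as well, with 61 genes higher and 33 lower; camera passed its threshold there once Pcgf6 was left out, and in no tissue with it.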

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

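The tests for testis RNA, for epididymal tissue, for shared calls, for correlations and for testis minus liver with the same split in both tissues, and with Alb as a term in brain were chosen after the results were seen; the other tests of this part were written down beforehand.

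Differences of the genotype effect between tissues drew attention to 16 values, each called by limma on 12 libraries. Testis minus liver, the log2 fold change differed by -7.07 for Mael, -4.20 for Syce1, -4.85 for Slc25a31, -2.58 for Ddx4, -2.01 for Tex11 and -2.83 for C1qtnf4, a secreted protein that measured 0.32 ± 0.22 FPKM in WT and 2.47 ± 0.38 in KO liver. Testis minus brain, it differed by -5.59 for Mael, -2.49 for Syce1, -3.72 for Slc25a31, -1.98 for Henmt1, -1.64 for Rbm46, -3.97 for Xlr4c, -4.24 for Xlr4b, -4.69 for Gm4779 and -4.99 for 8030474K03Rik, and by 2.49 for the pseudogene Rps4l. Over 13 alternatives Mael and Syce1 from liver, and Syce1, Slc25a31 and Xlr4c from brain, stayed called in all. C1qtnf4 stayed called in 5: voom (adjusted p = 0.0592), no filter (0.0611), a pseudocount of 0.01 (0.0561) and leaving out number 1, 2, 4, 5 or 6 (up to 0.244) ended its call. Tex11 stayed called in 7, its call ending with a pseudocount of 1 (0.866), the block by title number (0.0773) and without number 1, 2, 3 or 6 (up to 0.128). Ddx4 stayed called in 10, failing at pseudocounts of 0.01 and 1 (0.0530 and 0.545) and without number 2 (0.0555). From brain, Rbm46 stayed called in 7, failing with a pseudocount of 1 (0.895), the block (0.0535), all 18 libraries in 1 fit (0.223) and without number 2, 5 or 6 (up to 0.169). The remaining 7 differences each lost their call in 1 alternative: a pseudocount of 0.01 for Slc25a31 from liver (0.0991) and Mael from brain (0.0512), and all 18 libraries in 1 fit for the other 5, with adjusted p up to 0.416.

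Regroupings of the libraries decide little about these counts. Of 100 regroupings within tissues, 22 gave at least the 10 genes called for testis minus brain (highest other 14), so chance is not excluded for that count. Such regroupings also break any pairing by title number between brain and testis, and the same split in both was not run there. For testis minus liver 12 gave at least the 6 called (highest other 11), yet regrouping each tissue alone breaks the pairs of title numbers; with the same split in both tissues 1 of 10, the real one, gave 6 (highest other 2), too few splits for a share under 0.05. For brain minus liver, where limma called 0, each of the 100 reaches that count whatever the libraries hold, so nothing follows from it (highest other 38).

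Mael, Syce1 and Slc25a31 rose in KO liver and brain. Among other germ cell genes, Henmt1 (2.01) and Rbm46 (1.81) rose in brain and had too few reads for a test in liver (0 in WT and 4 in KO, and 7 and 55), Ddx4 (2.73) was called in liver when adjusted within the testis-specific set (adjusted p = 0.00440) and had a log2 fold change of 2.35 in brain, and Sycp3 in liver (-0.54) and Dazl in brain (-0.46) had log2 fold changes below 0 without being called; the list of germline targets was not called with an estimated correlation (adjusted p = 0.0789 and 0.222). Testis RNA in the KO libraries is argued against: Mael would need 2.88% of its testis FPKM in liver and 1.71% in brain, while the 20 most abundant genes of the testis-specific sets, fixed targets left out, showed a median excess of 0.991% and 0.768% of that share, and liver KO 4 had Mael at 18.8 FPKM with Prm1 at 0. Other scalings do not test the scaling as a cause: they moved the median of all genes by at most 0.0336, so the lowest log2 fold change of Mael, Syce1 and Slc25a31 under them, 2.526, could hardly have come out otherwise. What also stays open is a loss of PRC1.6 repression, the biological difference the design names, which these RNA levels are consistent with but do not test; smaller excesses of other testis genes in liver KO 5 and KO 6, with testis shares of 0.0456% and 0.0797%, may be traces of testis RNA.

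Other splits of the 6 libraries of a tissue number 10 with the real one, too few for a share under 0.05. In liver, 2 splits gave at least 3 genes (real 3, highest other 8), 3 gave at least 11 lists (real 11, highest other 15) and 1 gave 6 testis-specific genes (real 6, highest other 2). In brain, 2 gave at least 15 genes (real 15, highest other 15), 3 gave at least 11 lists (real 11, highest other 11) and 1 gave 5 testis-specific genes (real 5, highest other 4). Sharing 3 called genes between liver and brain was reached by 2 of 100 pairs of splits, the real one included (highest other 3). That share takes the tissues as split independently. Genes on or off by title number were divided alike across tissues, so it does not exclude chance. With the same split of the numbers in both tissues, 2 of 10 reached 3 (real 3, highest other 3), too few for a share under 0.05. Correlations of log2 fold changes were as high in 1 of these 10 splits between liver and brain, the real one (0.305, highest other 0.267), in 9 between liver and testis (real 0.0808, highest other 0.224) and in 10 between brain and testis (real 0.0409, highest other 0.184), again too few. Among liver splits that part all 3 pairs of liver libraries, as the real one does, the others called 0 genes; the split of 1, 4 and 5 from 2, 3 and 6, with 8, keeps a pair together. In brain the split that equals the real count sets WT 3, KO 5 and KO 6 apart, the libraries that carry Alb, and its calls include Alb, Ambp and Gc of hepatocytes and Prm2 and Tnp2 of sperm. With that division as a term, 12 genes were called in brain, 11 of them among the 15; Mael (adjusted p = 0.0104), Slc25a31 (0.0139) and Syce1 (0.0474) stayed past the threshold, and Rbm46 (0.0653), Klk6 (0.0547), Gabra2 (0.0663) and Obox3-ps7 (0.0653) did not. The log2 fold change of Rbm46 was 1.81 ± 0.19 without the term and 1.75 ± 0.20 with it (SE), that of Klk6 0.75 ± 0.08 and 0.77 ± 0.08, that of Gabra2 0.52 ± 0.06 and 0.52 ± 0.06 and that of Obox3-ps7 1.91 ± 0.20 and 1.85 ± 0.21. These calls therefore ended with folds within 1 SE of their former value, at a slightly larger SE and with 1 more term in the fit, and the division by Alb does not account for the folds.

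Camera called gene groups in KO testis, where testis WT 3 stands apart. Which lists were called depended on that library: without it 3 of the 7 stayed called in their direction (Hox genes, spermatogonia and epididymis). The number called hardly moved, at 6, because interferon response (median 0.16, adjusted p = 0.00818), macrophage and neutrophil (0.23, 0.00818) and peritubular, vascular and macrophage genes (0.15, 0.0170) were then called up. These calls used camera's preset correlation. An estimated correlation, which left 0 testis lists with all libraries, was not run without WT 3. The test for epididymal tissue in WT 3 did not decide, since 66.7% of the 12 measured epididymis genes were highest in it and the rest were not. That share counts genes near the floor, as Lcn9 and Cst11, among the rest, had at most 6 reads in any testis library. Defb21 and Rnase10, also among the rest, were highest in KO 4 and KO 5. Adam7 measured 0.0865, 1.47 and 8.20 FPKM in WT 1 to 3, and Defb2 0.136, 1.27 and 26.8. Both had 0 in every KO library. WT 2 thus held such transcripts as well, so the list's call without WT 3 does not speak against epididymal tissue. The summed level of the 12 genes was 67.6, 101 and 401 FPKM in WT 1 to 3 and 56.0, 66.1 and 60.8 in KO. The splits are again too few for a share under 0.05, with 4 giving at least 1 gene (real 1, highest other 9) and 6 at least 7 lists (real 7, highest other 12). An effect of Pcgf6 on the make-up of the testis stays open and was not tested beyond this.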

How the results depend on the processing

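Added after the data were seen were limma in place of a count model, pseudocounts of 0.01 and 1 FPKM, the block by column number, voom and the fit to 12 libraries for differences between tissues, the Alb term and the deposited sizes; a Wald test on counts and TMM scaling were not run. Of 180 alternatives for results that answer a comparison, 140 kept their side of the threshold or their count within 1.5 times; named genes did so in 103 of 117 alternatives in liver, 281 of 322 in brain and 27 of 34 in testis, and called lists, apart from the estimated correlation, in 87 of 99, 99 of 110 and 53 of 63. Other scalings left the count of genes in each tissue as it was.

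All 18 libraries in 1 fit called 107 genes in liver, 40 in brain and 37 in testis in place of 3, 15 and 1. Voom called 2 in testis and voom with quality weights 25 in brain and 5 in testis; with no filter testis had 0. An estimated correlation left 0 lists in liver, 0 in brain and 0 in testis. For differences between tissues, the planned fit over 18 libraries called 6 for brain minus liver, 16 for testis minus liver and 6 for testis minus brain. Brain minus liver had 1 with no filter, 2 with a pseudocount of 0.01 and 1 with a pseudocount of 1, and testis minus liver 3 with a pseudocount of 0.01. The germline difference in liver was 52.39 with deposited sizes and 17.20 CPM without Mael (34.6 otherwise). A minimum ratio of 1000 left 2 testis-specific genes in liver, and the brain median within 5 Mb without Pcgf6 was 0.03788, then past camera's threshold. Median-ratio sizes, the 1 other scaling run for lists, ended the calls of the epididymis (adjusted p = 0.0527, median -0.85 in place of -0.82) and round spermatid lists (0.0552, median 0.071 in place of 0.10) in testis; no filter those of imprinted (0.0849) and mitochondrial genes (0.211) in liver and lymphocyte genes in brain (0.775, median turning to 0.01471), which the Alb term ended too (0.156), as it did for ribosomal genes (0.550). The cause was not tested, except that fewer genes are tested under stricter filters.

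Leaving out 1 library gave 2 to 5 genes in liver (5 without WT 1 or WT 3), 8 to 11 in brain (8 without WT 2, KO 5 or KO 6, 9 without WT 3) and 0 to 6 in testis (6 without WT 1, 3 without WT 2, 0 without KO 4 or KO 5). Brain lists ran from 7 (without KO 6) to 15, liver lists from 10 to 15 and testis lists from 5 to 9. Brain minus liver had 0 to 2 (2 without number 3, 1 without number 6), and testis minus liver 3 to 12 (3 without number 2, 12 without number 4). Testis-specific genes ran from 4 to 37 in liver (4 without WT 3, 37 without KO 4) and 3 to 5 in brain (3 without KO 5 or KO 6). Reversed signs were seen for Sycp3 in brain (-0.1381 to 0.08364; 0.06924 without KO 4, 0.02689 without KO 5), ribosomal genes in brain (-0.07876 to 0.01014; 0.003491 without WT 2) and, without testis WT 3, ribosomal (-0.1785 to 0.02277) and elongating spermatid genes (0.01698 to 0.2375, camera turning down). Medians also changed sign for macrophage and neutrophil genes in liver (-0.1246 without WT 1), the piRNA pathway in liver (-0.0007499 without KO 4) and lymphocyte genes in brain (0.01741 without KO 5), where camera kept its direction. The cause was not tested; with 2 libraries in a group fewer samples carry each test.

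The replicate block by column number called 2 genes in liver, where it pairs the libraries, and 9 in brain and 1 in testis, where it is a hint only; in brain and testis not every library correlated best with its own number. In liver it ended the call of Slc25a31 alone. In brain Syce1 (adjusted p = 0.0936), Ide (0.113), Klk6 (0.144) and Rbm46 (0.157) were not called with it and Ddx4 was (0.00564), and in testis round spermatid genes were not (0.0786). The replicate block by title number called 0, 5 and 10 genes for brain minus liver, testis minus liver and testis minus brain; beside Tex11 it ended the call of Rbm46 for testis minus brain (adjusted p = 0.0535). At this depth germ cell genes with fewer than 10 reads per library, such as Dazl and Stk31 in liver, were not testable in the main fits.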

Other observations

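The tests for alleles, for carry-over between libraries and for the segment from Fgfbp3 to Pcgf6 were chosen after the pattern was seen; the other tests on Ide and Fgfbp3 were written down beforehand.

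The partners of Pcgf6 in PRC1.6 were expressed in WT and KO libraries of all 3 tissues. Mga, the scaffold of the complex, measured 3.12 ± 0.38 FPKM in WT and 3.70 ± 0.21 in KO liver, and 4.62 ± 0.07 and 4.62 ± 0.24 in brain. L3mbtl2, which binds chromatin, measured 4.77 ± 0.54 and 5.20 ± 0.57 in liver and 7.71 ± 0.65 and 7.39 ± 0.53 in testis, and the DNA-binding subunit E2f6 measured 6.88 ± 0.64 and 7.56 ± 0.57 in brain and 1.62 ± 0.26 and 1.25 ± 0.13 in testis. None of them was called by limma, and the list of subunits other than Pcgf6 had camera adjusted p values of 0.438 in liver, 0.832 in brain and 0.560 in testis.

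Of the 6 X-linked Xlr genes tested in brain, Xlr4b and Xlr4c were called and the others did not pass: Xlr3a measured 0.35 ± 0.05 FPKM in WT and 1.30 ± 0.33 in KO (log2 fold change 1.6 ± 0.20, adjusted p = 0.0637), Xlr3b 1.67 ± 0.75 and 6.88 ± 0.46 (adjusted p = 0.128), Xlr4a 0.20 ± 0.29 and 2.85 ± 0.34 (adjusted p = 0.149) and Xlr 0.18 ± 0.05 and 0.24 ± 0.06 (adjusted p = 1.00). In liver, Xlr4b measured 0.16 ± 0.25 and 5.02 ± 2.04 FPKM (adjusted p = 0.349), Xlr4c 0.11 ± 0.09 and 0.75 ± 0.41 (adjusted p = 0.553) and Xlr3a 4.57 ± 2.48 and 5.82 ± 1.2 (log2 fold change 0.46, adjusted p = 1.00). In testis, Xlr4b measured 0.73 ± 0.15 and 0.81 ± 0.06 and Xlr3a 0.28 ± 0.06 and 0.28 ± 0.01. Their near-identical sequences leave the division of reads between them uncertain. Nnt, which carries a deletion in the C57BL/6J substrain, measured 0.19 ± 0.04 FPKM in WT and 0.17 ± 0.07 in KO liver. Gabra2, whose level is lowered by a variant of that substrain, was higher in KO brain at 8.38 ± 0.25 against 5.81 ± 0.14 FPKM.

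Some genes were on in part of the libraries and off in the rest, in the same numbers across tissues, most of them without regard to genotype. Rps13-ps1, a ribosomal pseudogene, measured 0.981, 62.3 and 66.9 FPKM in liver WT 1 to 3 and 1.92, 1.32 and 51.7 in KO 4 to 6, and it divided the numbers alike in brain and testis, as did Gm10020; Gm9008 was on in 1, 2 and 4 and near 0 in 3, 5 and 6. Such genes, with a gap of at least 2 on the log2 scale, shared their division in 8 of 12 genes (66.7%) between brain and liver, 10 of 10 between testis and liver and 7 of 9 (77.8%) between testis and brain, with exact permutation p of 0.00139, 0.00139 and 0.00278 over 720 orders of the numbers, the smallest they can give being 0.00139. Of the 8, Mael and Slc25a31 follow genotype; of 5 genes that divided alike in all 3 tissues, 0 did. RNA carried over between libraries of 1 number is argued against, because the highest share of another tissue in any library was 0.209%. A candidate explanation is that the numbers name mice that carry different alleles. Single genes that follow genotype, such as Rps4l in liver and brain, Gm5815, and Gabra2 in brain, would be open to the same reading. In testis Rps4l did not follow genotype, at 69.3, 69.5 and 119 FPKM in WT and 71.6, 73.3 and 74.8 in KO. Of the 5 genes that divided alike in all 3 tissues, 3 are not protein-coding, and reads of such copies are uncertain.

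Ide and its neighbour Fgfbp3 lie about 10 Mb from Pcgf6 and were lower in every KO than in every WT library of all 3 tissues. Ide differed by -0.68 in liver, -0.67 in brain and -0.33 in testis on the log2 scale, and Fgfbp3, a binding protein of growth factors, by -0.79, -0.71 and -1.10. A copy number difference of the whole interval between them is argued against, since the genes between them had a median log2 fold change of 0.01818 (SD 0.250) over 12 values. These are a few genes repeated over the 3 tissues, with 5 of the 12 values below 0. The lower ones include Btaf1 in brain at -0.48 ± 0.07 (SE, limma adjusted p = 0.149), and a difference of part of the interval was not tested. A linked segment around Pcgf6 that differs between WT and KO mice may contribute and stays open: of 1000 random windows, 63.3% had a mean correlation between tissues as high as genes within 5 Mb of Pcgf6 (-0.0131 over 71 genes), a window that does not reach Ide or Fgfbp3, and 39.5% as high as the 10.1 Mb from Fgfbp3 to Pcgf6 (0.0608 over 97 genes, with Fgfbp3, Ide and Pcgf6 left out). Within 10 Mb, without Pcgf6, 7.14% of 168 genes in brain had an unadjusted p under 0.05 against 4.44% elsewhere; the shares were 3.77% in liver and 3.52% in testis.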
